A study of Homo sapiens with 2 samples.

How the data were processed

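Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open chromatin, in U2OS cells, an established human osteosarcoma line. There were 2 libraries, 1 from cells infected with a control short hairpin (sh-ctrl) and 1 from cells infected with a hairpin against the long non-coding RNA Vanguard (sh-VNGD). Each group therefore held 1 library, and the groups were taken from the treatment given in the labels. Libraries were sequenced on a BGISEQ-500 instrument, per the labels' protocols.

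Peaks were called with MACS version 2.1.0.20150731 on each library separately and without a control library, per the file headers. The submitters' processing notes name Bowtie2 2.2.5, MACS2 2.1.2, deepTools and the hg38 and GRCh38.p13 builds. The MACS version in the notes thus differs from that in the headers. Per the file headers, 5' ends of tags were shifted by 100 bp and extended to 200 bp, which centres each tag on the insertion site, and 1 tag per position was kept. The q cutoff was 0.05, the effective genome size 3.27e+09 and the local background window 10000 bp, per the file headers. How alignments were filtered is not given in the sources used here.

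Per the file headers, 51628228 tags were read for sh-ctrl and 48164322 for sh-VNGD. After removal of repeated positions, 22931980 and 31326715 were kept, with redundant rates of 0.56 and 0.35. The deposited pileup is a signal, the number of tags covering the peak summit, unscaled for depth, and 100% of its values were exactly whole, with no tolerance. The −log10 p and −log10 q values and the fold enrichment over local background are the authors' own values for each peak, as deposited, and were used to rank and filter peaks within a list. The deposited lists came in 2 formats, and the shorter format repeated the −log10 q and the pileup signal of the longer one line by line.

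Peaks on chromosomes 1 to 22, X and Y were analysed. Shares of peaks overlapping the other library by at least 1 bp were given with Wilson 95% intervals, beside the share after moving the peaks by 50 kb. Peaks of both libraries were then merged into regions. The deposited peak names carried no genes, so genes came from a RefSeq table of GRCh38.p14, which holds the outer bounds of 20033 protein-coding genes without strand or exons. Promoters could therefore not be separated from the other gene end. Regions within 1000 bp of each outer end were sought, and the end with the higher summed pileup scaled to kept tags was used. This replaced the transcription start sites of the plan. Exon and intron classes were replaced by gene end, gene body and outside. Inner promoters are missed by this rule, and 3445 genes shared their region with another gene. Motif shares, planned for 15 motifs, were not computed because no reference genome sequence was used here.

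The gene ratio was the log2 of the sh-VNGD pileup over the sh-ctrl pileup in the same region, each divided by the kept tags of its library. Its interval was the exact Clopper-Pearson 95% interval for a ratio of counts. Ratios required a peak of both libraries in the region. A gene counted as having a peak in 1 library only when no region touching the chosen end held a peak of the other. Assigning each library's own peaks to the window, as first planned, made genes appear in 1 library only when a peak touched the window edge in that library alone. Merging was adopted after both readings had been seen, and the rule for a peak in 1 library only was corrected after the named genes had been seen. Own windows gave 13904 genes with a peak in both libraries, 641 in sh-ctrl only and 1025 in sh-VNGD only. Merged regions gave 13987, 594 and 989. The lowest 10 genes by ratio shared 8 members between the readings, as did the highest 10.

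The gene lists (24), the rule for named genes, the comparisons and the first set of alternatives were fixed before the data were examined, and 527 of the 529 list entries were matched to symbols. A list's median ratio was placed among 10000 random lists of the same size matched on pileup in 20 bins, as a description of these libraries. The rule for named genes took the 10 highest and 10 lowest ratios among genes with a pileup of at least 30 in either library. It also took the 5 genes with the highest pileup among those with a peak in 1 library only, for each library, and the 2 highest and 2 lowest members of each list with members found in 1 library only. HMGB1, CDKN1A, GAPDH, RUNX2, ATM, BRCA1 and XRCC6 were always named. Finally it took the 5 highest unshared peaks per library over 10 kb from any gene end. Results for 2 genes and 1 gene list are not reported here.

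No p-values were computed, since 1 library per group gives no spread between replicates. All intervals cover counting error only. The ratio and its interval were tested on simulated pileups for 13915 genes. Simulated counts were drawn with counting error only around the sh-ctrl pileups, with sh-VNGD raised by the ratio of kept tags. Intervals covered the simulated ratio in 95.8% of genes, since this counting error is the one they assume. The interval lay beyond 0 for 96% of genes set to 0.25-fold, 78% at 0.5-fold, 92% at 2-fold and 100% at 4-fold. Alternatives included −log10 q thresholds of 5 and 10, a 50% reciprocal overlap, equal numbers of peaks, a window of 500 bp, scaling to the median of genes and fold enrichment in place of pileup. Own windows, the assignment first planned, were kept as an alternative to the merged regions adopted later. Further alternatives were chosen after seeing the data, namely the histone list without its 4 linker histone genes, either gene end, tags within 10 kb recovered from the authors' fold enrichment, a correction for occupied positions, each region once, and sh-VNGD peaks thinned to the sh-ctrl depth. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.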

Results

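Accessible chromatin was profiled by ATAC-seq in U2OS osteosarcoma cells carrying a control hairpin (sh-ctrl) or a hairpin against the glucose deprivation-responsive long non-coding RNA Vanguard (sh-VNGD). Each group had 1 library, so differences below have no replicate check and intervals cover counting error only. ATAC-seq measures accessibility and not RNA, so the knockdown itself could not be checked here. The sh-ctrl library kept 22931980 tags and the sh-VNGD library 31326715, a ratio of 1.37. Fewer tags had been read for sh-VNGD, at 48164322 against 51628228, but 35% of them were repeats of a position compared with 56% in sh-ctrl. Coordinates are those of the deposited peak lists on GRCh38.

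The first comparison asked how many regions were accessible in each library. The sh-VNGD library had 302466 peaks on the assembled chromosomes and the sh-ctrl library 213285, a ratio of 1.42. Covered length was 95 Mb in sh-VNGD and 71.3 Mb in sh-ctrl, a ratio of 1.33. The number of high peaks was nearly equal, with 30526 peaks of pileup 50 or more in sh-VNGD and 29631 in sh-ctrl. Peaks with a fold enrichment of 10 or more, by the authors' values, made up 9.38% of the sh-VNGD list and 16.3% of the sh-ctrl list. The median pileup was 16 tags in sh-VNGD and 15 in sh-ctrl. The sh-VNGD list was longer where the kept depth was greater, so the count of peaks follows depth as well as group.

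The next comparison asked whether the same regions were open. Of the sh-ctrl peaks, 72.2% (Wilson 95% interval 72.0 to 72.4) overlapped a sh-VNGD peak, and 51.1% (50.9 to 51.3) of sh-VNGD peaks overlapped a sh-ctrl peak. After a shift of 50 kb the shares were 7.94% and 5.67%. Strong peaks were shared almost completely. At a −log10 q of 50 or more, 99.9% of 18972 sh-ctrl peaks and 100% of 16935 sh-VNGD peaks overlapped. Below 5, the shares were 49.2% and 24.3%. The peaks found in 1 library only were low, with a median pileup of 12 tags among 59217 sh-ctrl peaks and 14 among 147823 sh-VNGD peaks. Shares depended on the threshold, and with equal numbers of peaks they were 61.9% and 61.8%.

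**Figure D1:**
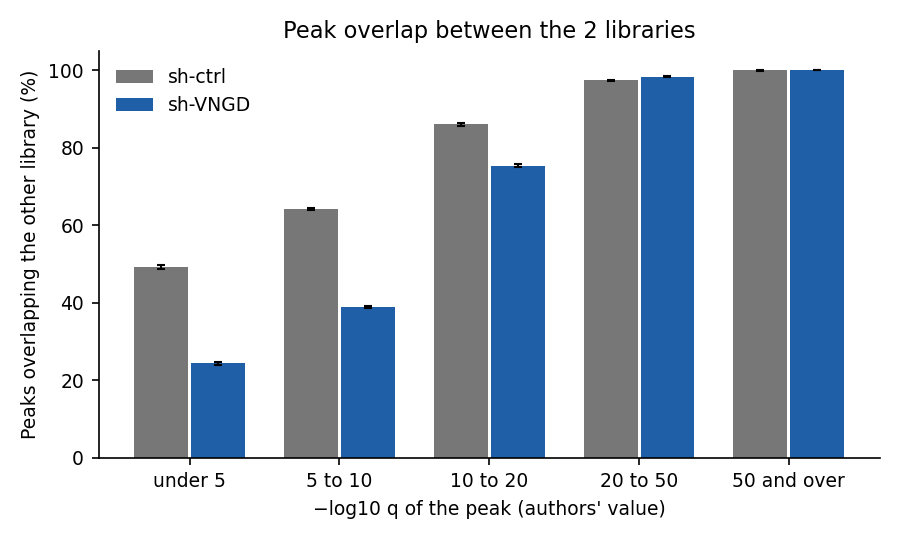
Percentage of each library's peaks that overlap a peak of the other library (vertical axis) by the authors' −log10 q (horizontal axis), with grey bars for sh-ctrl, blue bars for sh-VNGD and Wilson 95% intervals. The shares run from 49.2% and 24.3% in the weakest class to 99.9% and 100% in the strongest.

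Peaks at the ends of protein-coding genes took a smaller share of the sh-VNGD list. Summits within 1000 bp of a gene end made up 7.91% of sh-ctrl peaks (7.80 to 8.03) and 6.16% of sh-VNGD peaks (6.07 to 6.24), against 3.51% and 3.30% for summits moved by 50 kb. Gene bodies held 44.3% and 43.8%, and regions outside protein-coding genes held 47.8% and 50.1%. Among peaks found in 1 library only, the gene-end shares were 2.88% in sh-ctrl and 2.1% in sh-VNGD. With equal numbers of peaks the sh-VNGD share was 7.77%, so the difference between the full lists went with the longer sh-VNGD list.

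Among 152097 regions with a peak in both libraries, the strong regions had less signal for their depth in kept tags in sh-VNGD. Regions with a mean pileup of 50 or more had a median log2 ratio of −0.46, and 93.0% of these 28851 regions lay below 0. The median was −0.19 in regions with a mean pileup under 15, −0.13 from 15 to 20 and −0.49 in those from 100 to 150. Every region needed a called peak in both libraries, and the lowest called pileups were 6 tags in sh-ctrl and 7 in sh-VNGD. Calling thus limits the ratios that low regions can take, so part of the difference with height may be built in. Without scaling to kept tags, strong regions had about equal pileups, with a median log2 ratio of −0.01 in regions of mean pileup 50 or more. The direction at strong regions therefore rests on scaling to kept tags.

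**Figure D2:**
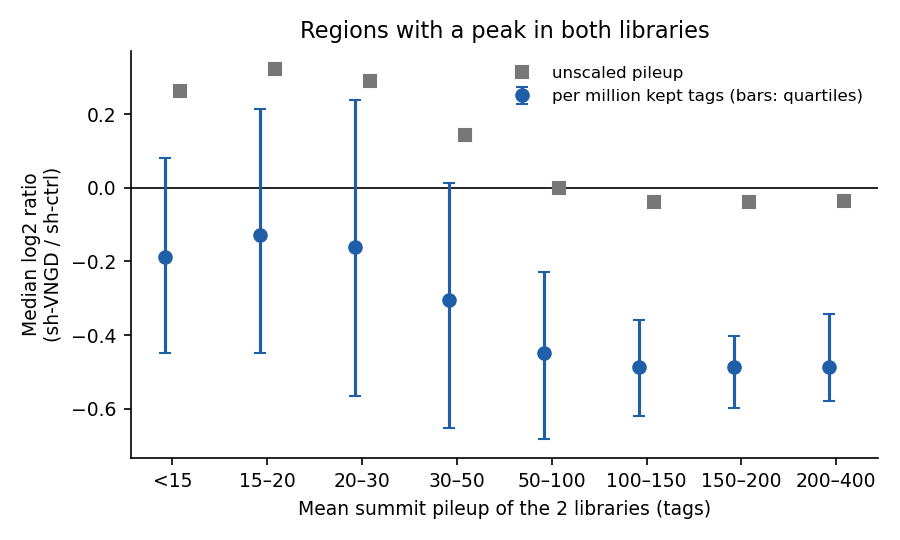
Median log2 ratio of sh-VNGD to sh-ctrl summit pileup (vertical axis) in regions with a peak in both libraries, by mean pileup in tags (horizontal axis), with blue points scaled to kept tags, bars for the quartiles and grey squares for unscaled pileups. The scaled median is −0.19 below a mean pileup of 15, −0.13 from 15 to 20 and −0.49 from 100 to 150. Only regions with a called peak in both libraries enter, which limits the ratios of low regions.

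At gene ends, the next comparison asked which genes differed in accessibility. Of 20033 protein-coding genes, 13987 had a peak in both libraries (69.8%), 594 in sh-ctrl only (2.97%), 989 in sh-VNGD only (4.94%) and 4463 in neither. The 13915 genes with a peak of both libraries in the same region had a median log2 ratio of −0.45 (quartiles −0.64 and −0.26). Ratios of single genes below are relative to that median, which equals comparing unscaled pileups. Medians of gene lists are given before centring, so the level of all genes beside them is −0.45. Random lists matched on pileup had levels of their own, such as −0.51 for cell cycle genes and −0.40 for interferon response genes. Percentiles refer to those matched lists. Relative to it, the interval lay wholly below for 618 genes (4.44%) and wholly above for 586 (4.21%), or 8.65% together. The 95.8% coverage in simulated genes is no yardstick for this share. Simulated counts held only the counting error that the interval assumes. Before this centring, intervals lay below 0 for 6651 genes and above 0 for 57.

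The lowest relative log2 ratios were those of GPX2, a glutathione peroxidase of epithelia, at −1.85 (−2.78 to −1.0), EXOC3L4 at −1.81 (−2.56 to −1.11) and GDPD3 at −1.71 (−2.21 to −1.23). The GPX2 region at chromosome 14, 64938571 to 64938917, had a pileup of 54 tags in sh-ctrl and 15 in sh-VNGD, and the GDPD3 region at chromosome 16, 30104121 to 30105113, had 157 and 48. The size of these and other low values depended on the measure, though every measure given here put them below all genes. Before centring, all genes stood at −0.45 by pileup, −0.11 by fold enrichment and −0.32 by tags within 10 kb. In that order, EXOC3L4 was at −2.26, −0.67 and −1.73, GDPD3 at −2.16, −1.04 and −1.20, and GPX2 at −2.30, −1.51 and −0.79. Likewise, NR2E3 was at −2.15, −0.83 and −1.50, LRRN4 at −1.99, −1.0 and −1.13, and C9orf152 at −1.96, −0.77 and −1.37. Relative to all genes by pileup, further low values were as follows. NR2E3, a photoreceptor nuclear receptor, stood at −1.70, CXorf65 at −1.56, LRRN4 at −1.54, C9orf152 at −1.51, MYPN, a sarcomere protein, at −1.49 and the sperm channel subunit CATSPER3 at −1.46. LYZL2, also at −1.54, depended on the assignment, with a log2 ratio before centring of −1.99 in merged regions and −1.13 by own windows. The highest was CAPSL, at 2.03 (1.41 to 2.69), with 27 tags in sh-ctrl and 110 in sh-VNGD at chromosome 5, 35938504 to 35938929. LOC128966731 followed at 2.02, the retinoid receptor gene RXRG at 1.95, the netrin receptor gene DCC at 1.93, DDC at 1.83 and TWIST1, a mesenchymal transcription factor, at 1.77 (0.82 to 2.84). FLG2 stood at 1.71, MAP1S at 1.70, and NAT8 and ASMTL at 1.62. Before centring, TWIST1 was at 1.32 by pileup, 1.12 by fold enrichment and 0.42 by tags within 10 kb. In the same order, FLG2 was at 1.26, 1.03 and 0.39, and MAP1S at 1.25, 1.0 and 0.35. Apart from CAPSL, these high ratios started from 8 to 15 tags in sh-ctrl, and reads of LOC128966731, near a chromosome end, may be shared with copies elsewhere.

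Genes with a gene-end peak in sh-ctrl only were led by LFNG, a Notch-modifying glycosyltransferase, with 84 tags at chromosome 7, 2527815 to 2528381. TNFRSF6B, a decoy receptor, had 75 tags, FAM83A 66, the cardiac troponin gene TNNT2 61 and the iodide transporter gene SLC5A5 60. Genes with a peak in sh-VNGD only were led by DQX1 with 60 tags at chromosome 2, 74526241 to 74526486, then RPEL1 with 51, ZNF665 with 48, and DUX4 and the interleukin receptor gene IL2RB with 47 each. A missing peak is not a count of 0, since calling also depends on the local background. The value of DUX4, a gene in repeated copies, is uncertain because reads may be shared among them.

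Histone genes, which encode the core and linker proteins that package DNA, had lower gene-end pileups in sh-VNGD as a group. Of the 34 with a ratio, 33 lay below the median of all genes, and 23 had intervals wholly below it. The median log2 ratio was −0.94, or −0.49 relative to all genes, below each of 10000 matched random lists. The linker histone gene H1-5 was lowest at −1.45 relative to all genes (−2.15 to −0.80), with 74 tags in sh-ctrl and 27 in sh-VNGD, and H2BC7 stood at −1.07 (−1.57 to −0.58). The exception was H4C2 at 0.02 (−0.47 to 0.51). Without its 4 linker histone genes, the list median relative to all genes was also −0.49. These genes lie in clusters on chromosome 6 and shared 27 regions, so they are not independent. Tags within 10 kb were lower still, at a median log2 ratio of −1.33 against −0.32 for all genes, and the authors' fold enrichment over that local background was higher in sh-VNGD, at a median of 0.15 against −0.11.

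**Figure D3:**
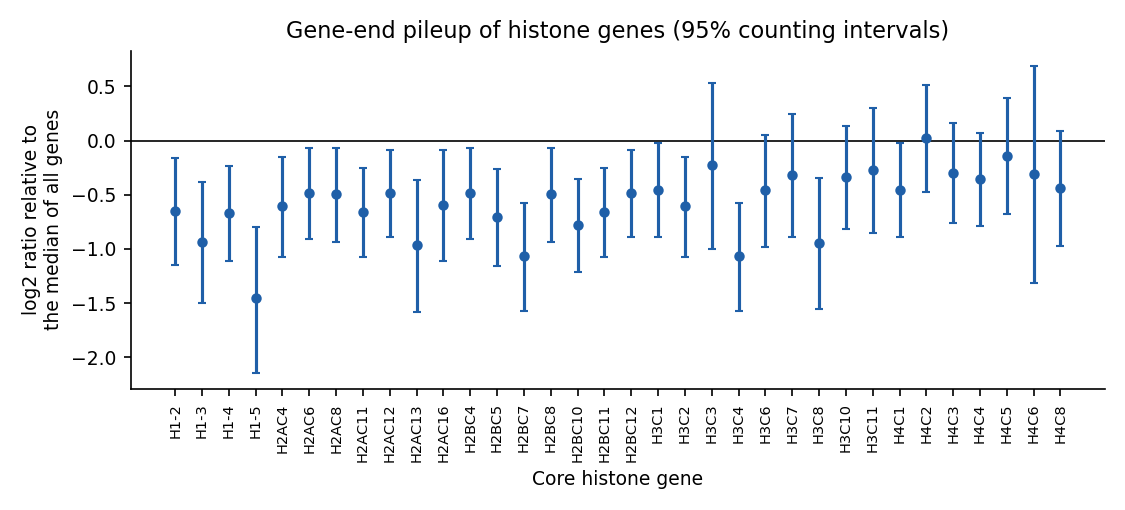
Gene-end log2 ratio of sh-VNGD to sh-ctrl pileup relative to the median of all genes (vertical axis) for 34 histone genes (horizontal axis), with bars for 95% counting intervals. Of these, 33 lie below 0, and H1-5 is lowest at −1.45.

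Cell cycle and replication genes were also low in sh-VNGD. The 25 cell cycle genes with a ratio had a median of −0.62 against −0.45 for all genes and −0.51 for matched lists, at percentile 0.94. CDT1, which licenses replication origins, was at −1.02 relative to all genes (−1.47 to −0.59), with 136 tags in sh-ctrl and 67 in sh-VNGD, and cyclin B2 (CCNB2) was at −0.56 (−1.06 to −0.07). BUB1 stood at 0.38 and CCNE1 at 0.10, both with intervals spanning 0, and ORC1 had a peak in sh-VNGD only, of 15 tags. With fold enrichment in place of pileup, the percentile of the list was 9.80, and CDT1 had a log2 ratio of −0.13 against −0.11 for all genes.

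CDKN1A, an inhibitor of cyclin-dependent kinases, had a gene-end peak in sh-VNGD only, of 36 tags at chromosome 6, 36676335 to 36676603. Inside the gene, both libraries had a higher peak, of 99 tags in sh-ctrl from 36678411 and 108 tags in sh-VNGD from 36678401. Further inner peaks had 24 tags in sh-ctrl and 64 in sh-VNGD from 36680412 and 36680265, and 59 and 45 from 36682503 and 36682813. A peak of 31 tags from 36679122 was called in sh-ctrl only. The gene table held no start sites, so which of these peaks marks a promoter cannot be told here. The local background at the sh-VNGD gene-end peak was 12.1 tags.

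DNA repair genes, the process named in the study's title, lay within the central 95% of matched lists as groups when pileups in merged regions were compared. Against −0.45 for all genes, medians were −0.56 for homologous recombination (22 genes, percentile 10.6), −0.51 for end joining (19 genes, 35.5), −0.55 for base excision repair (21 genes, 13.9) and −0.44 for nucleotide excision repair (22 genes, 68.7). Mismatch repair stood at −0.49 (13 genes, 37.1), Fanconi anaemia genes at −0.59 (16 genes, 5.66) and DNA damage signalling at −0.56 (20 genes, 10.1). Of 131 distinct genes in these lists, 8 had intervals wholly below the median of all genes and 1 wholly above it. Among all 13915 genes with a ratio, the shares were 4.44% below and 4.21% above, so such intervals were not particular to repair genes. Relative to all genes, the nuclease gene DNA2 was at −0.89 (−1.73 to −0.09), the checkpoint kinase gene CHEK1 at −0.63 (−1.08 to −0.19), HUS1 at −0.60 (−1.11 to −0.11), XRCC2 at −0.52 (upper bound −0.01) and MUTYH at −0.49 (−0.91 to −0.08). FANCI, USP1 and WEE1 also had intervals below 0. FANCE was at 0.54 (0.09 to 0.99). SHLD2 stood at 0.42, MDC1 at 0.54 and MLH3 at 0.72, with intervals spanning 0, as did SHLD1 at −0.74 and MNAT1 at −0.60. BRCA1 stood at −0.09 (−0.55 to 0.37), ATM at −0.22 (−0.60 to 0.16) and XRCC6, which encodes a Ku subunit, had 104 tags in each library. MRE11 had a peak in sh-VNGD only, of 14 tags. Other readings put some lower: homologous recombination by tags within 10 kb and Fanconi anaemia genes by own windows, the assignment first planned, both stood at percentile 2.1. CHEK1 had a fold enrichment log2 ratio of −0.09, near that of all genes.

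Chromatin remodeller and architectural lists also lay within their matched ranges when pileups in merged regions were compared. The SWI/SNF list had a median of −0.54 (22 genes, percentile 17.4), the ISWI, CHD and INO80 list −0.53 (26 genes, 19.8) and the HMG box and architectural list −0.56 (16 genes, 15.6, but 0.30 by tags within 10 kb). CHD4, the ATPase of the NuRD complex, was at −0.98 relative to all genes (−1.59 to −0.39), with 73 tags in sh-ctrl and 37 in sh-VNGD. Before centring, its log2 ratio was −1.43, but −0.84 within 500 bp and −0.42 by fold enrichment. SMARCD3 was at 1.23 (0.38 to 2.15) and SS18 at −0.47 (upper bound −0.004), and PBRM1, INO80 and BRD9 stood at 0.28, 0.37 and −0.37 with intervals spanning 0. HMGB1, an architectural DNA-binding protein, was at −0.23 (−0.56 to 0.11) and HMGB2 at 0.07 (−0.27 to 0.41). SMARCB1 and ACTL6B had a peak in sh-ctrl only, of 7 and 21 tags.

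Metabolic and stress lists lay within the matched ranges. Glycolysis genes had a median of −0.50 (21 genes, percentile 38.1), AMPK and autophagy genes −0.47 (23 genes, 60.8), stress response genes −0.55 (21 genes, 15.2) and interferon response genes −0.43 (20 genes, 37.7). Over the readings, percentiles ran from 19.8 to 95.2 for AMPK and autophagy genes and from 26.3 to 95.7 for interferon response genes. PGK1, a glycolytic kinase, stood apart from its list at 0.78 (lower bound 0.51), with 184 tags in sh-ctrl and 315 in sh-VNGD. Its fold enrichment, however, gave a log2 ratio of −0.08. With 1 tag kept per position, only 400 positions lie within reach of a summit, so the counting interval is uncertain at 315 tags. GAPDH was at −0.22 (−0.60 to 0.15), and HK1 had a peak in sh-ctrl only, of 14 tags. The stress gene TRIB3 was at −0.79 (−1.45 to −0.15), and the interferon-induced genes OAS1 and BST2 at 0.90 (0.12 to 1.72) and 0.69 (0.15 to 1.25).

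Ribosomal protein genes had a median of −0.58 (35 genes, percentile 2.09), with RPS3 lowest at −1.07 relative to all genes (−1.48 to −0.66) and RPS10 highest at 0.50 (−0.02 to 1.02). By fold enrichment the ribosomal list stood at percentile 31.6. Osteoblast and mesenchymal genes had a median of −0.50 (12 genes, percentile 13.1, but 35.6 by own windows). The matrix gene FN1 was at −1.0 (−1.56 to −0.46) and COL1A1 at −0.33 (−0.78 to 0.13). The highest were TWIST1 at 1.77 (0.82 to 2.84) and COL1A2 at 0.79 (−0.36 to 2.01). BGLAP had a peak in sh-ctrl only, of 32 tags, and ALPL and PRRX1 in sh-VNGD only, of 15 and 10 tags. RUNX2 had no peak at either outer gene end in either library. Immediate early genes had a median of −0.38 (17 genes, percentile 96.5), with MYC at −0.61 (−1.0 to −0.22) and IER3 at 0.80 (−0.06 to 1.69). By tags within 10 kb, immediate early genes lay below all genes, at −0.41 against −0.32 (percentile 18.9). By summit pileup, immediate early genes lay inside the central 95% of their matched lists. Among the 24 lists examined, 4 lay below that range and 1 above it.

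Markers of other cell types were examined in the same way. Haematopoietic markers had a median of −0.79 against −0.45 for all genes, at percentile 0.71, over 7 genes only, with HBA1 at −0.93 relative to all genes (−1.60 to −0.28) and CD8A at −0.54 (−0.97 to −0.11). That list stood at percentile 26 by fold enrichment and 28.5 by tags within 10 kb. Keratinocyte and epithelial markers had a median of −0.42 (12 genes, percentile 80.8), with KRT8 at −0.54 (−0.85 to −0.23) and TP63 at 1.54 (0.51 to 2.68). That percentile depended on the reading: it was 0 among genes with a pileup of at least 30, 0.50 by tags within 10 kb and 97.2 by fold enrichment. Neuronal markers stood at −0.54 (9 genes, percentile 18.1) and hepatocyte markers at −0.19 (6 genes, percentile 86.3). Neuronal markers lay above all genes within 500 bp, at −0.28 (percentile 82.9), and stood at percentile 53.4 by own windows and 91.4 by fold enrichment.

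**Figure D4:**
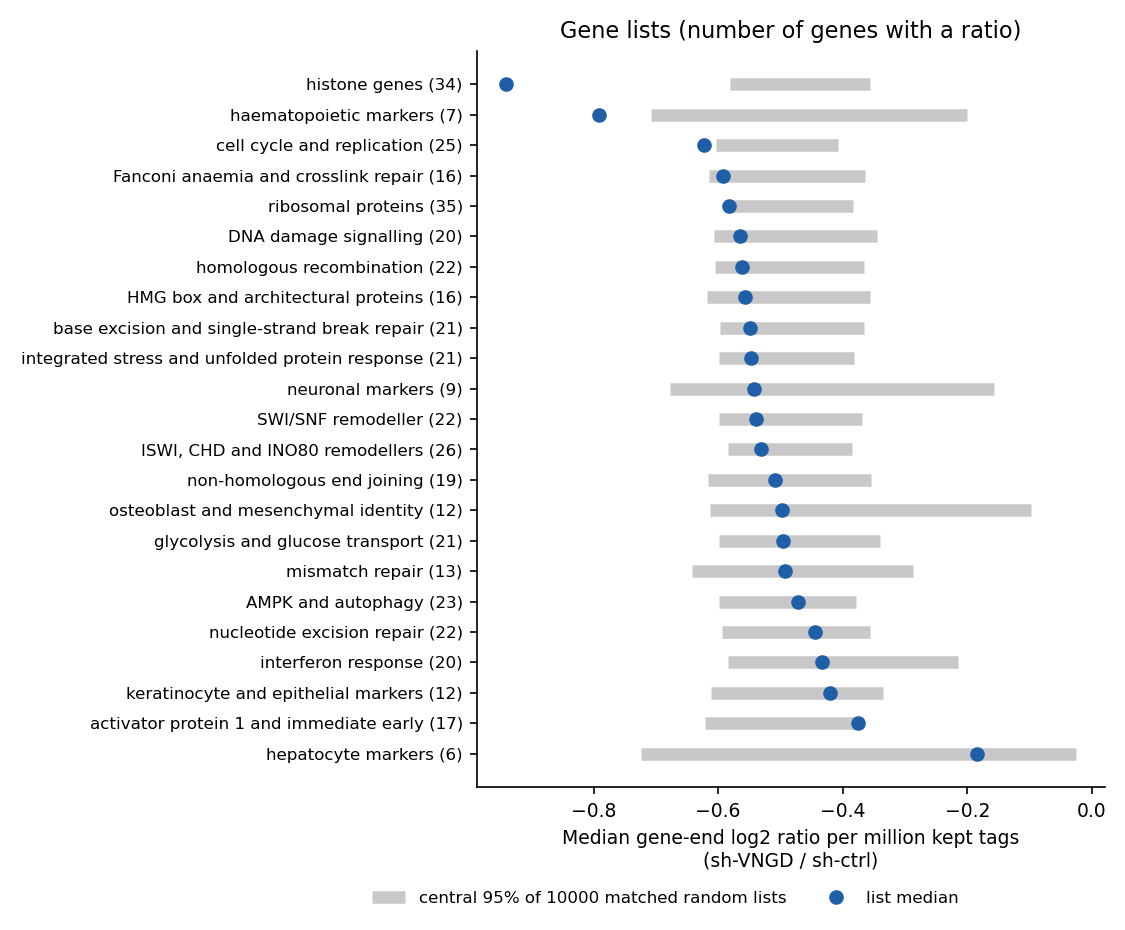
Median gene-end log2 ratio of sh-VNGD to sh-ctrl pileup scaled to kept tags (horizontal axis) for 23 gene lists (vertical axis, with the number of genes), beside grey bars for the central 95% of 10000 random lists matched on pileup. Histone genes lie at −0.94 and cell cycle genes at −0.62, both outside their matched ranges.

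Away from gene ends, the last comparison asked where peaks of 1 library lay. The highest unshared sh-ctrl peak over 10 kb from any gene end had 112 tags, at chromosome 17, 61231336 to 61231710, inside BCAS3. Others lay inside EEIG1 (104 tags), BTD (89 tags) and PIEZO1 (86 tags), and PIEZO1 also held an unshared sh-VNGD peak of 88 tags at chromosome 16, 88758280 to 88758598. The 3 highest unshared sh-VNGD peaks over 10 kb from any gene end lay together on chromosome 4, outside genes. They were led by 111 tags at 49122634 to 49122865, 60.7 kb from CWH43. Another of 88 tags lay on chromosome 17, 268.4 kb from KCNJ18. Their fold enrichments were 2.63, 2.49, 2.33 and 2.86, below the sh-VNGD list median of 5. Values were 3.96 at the highest BCAS3 peak, 5.17 in EEIG1, 7.56 in BTD, and 2.35 (sh-ctrl) and 3.80 (sh-VNGD) in PIEZO1. Reads of the sh-VNGD peaks outside genes on chromosomes 4 and 17 may be shared with copies elsewhere, which was not tested. A missing peak is again not a count of 0. The ratio of sh-VNGD to sh-ctrl peaks was 1.59 (exact 95% interval 1.55 to 1.63) on chromosome X and 1.28 (1.24 to 1.33) on chromosome 19, the highest and lowest. Among 2901 windows of 1 Mb with at least 50 peaks in the libraries together, and a median ratio of 1.44, the lowest ratio was on chromosome 6 from 59 to 60 Mb, at the centromere, with 108 sh-ctrl peaks and 10 sh-VNGD peaks. The window from 58 to 59 Mb had 60 and 25. The highest was on chromosome 7 from 62 to 63 Mb, also near the centromere, with 11 and 44. Centromeric sequence is repetitive, so the positions of such peaks are uncertain.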

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

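Every test in this part was chosen after its result or a closely related value was seen, except the depth test, whose bounds were written after the peak counts were seen and before thinning was run. The peaks on sequences other than the assembled chromosomes, which the comparisons left out, made up 5.82% of the sh-VNGD list (5.74 to 5.90) and 5.38% of the sh-ctrl list (5.28 to 5.47). Of these 18685 and 12119 peaks, 45.1% and 69.9% overlapped a peak of the other library.

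More peaks were called in the sh-VNGD library, at a ratio of 1.41 at a −log10 p of 6 or more. Pileups and local backgrounds of the called sh-VNGD peaks were thinned to the sh-ctrl tag total, and peaks were not called again. This lowered the ratio to 1.051, just above the bound set beforehand for depth and below the bound set against it. The thinned ratio was 1.26 at a −log10 p of 4, 0.94 at 8 and 0.88 at 10, so greater depth may account for part of the excess, and its part in weak peaks cannot be told apart from a difference between the groups. The design held 1 library of each kind, which keeps this open.

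Histone genes had lower gene-end pileups than other genes in sh-VNGD, although their fold enrichment was higher (percentile 100). Their peak height is argued against as the reason, since 0 of 10000 lists matched on pileup were as low (percentile 0). A regional difference over the chromosome 6 clusters may contribute, since 11 shared regions away from histone genes were lower than matched regions by a median log2 difference of −0.51, but the interval, −0.76 to 0.04, leaves it open. Tags within 10 kb of the histone genes were lower too, at a median of −1.33 against −0.32 for all genes. Those windows hold the gene-end peaks as well, but they were lower than the summit pileups, at −0.94 against −0.45 for all genes. The lower signal was thus not limited to the summits, while how far it reached beyond the peaks was not tested. A difference shared with other cell cycle genes is consistent with the percentile of 0.94 for that list, although fold enrichment gave 9.80, and ribosomal protein genes (2.09) and haematopoietic markers (0.71) were low too. Library and group remain confounded, and an effect of the knockdown was not tested apart from the library.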

How the results depend on the processing

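Merged regions were adopted, in place of the own windows first planned, after the results were seen. Either gene end, tags within 10 kb, occupied positions, each region once, thinning and the histone list without linker histones were also chosen then. With 1 library per group leaving out a replicate or splitting the samples was impossible, and the cause of each difference below was not tested unless given. No paired analysis was possible because each group held 1 library. The motif alternatives were not run.

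At a −log10 q of 10 or more, peaks numbered 84247 in sh-ctrl and 97238 in sh-VNGD, fewer by construction. Their overlap with all peaks of the other library was 93.0% and 86.9%, and gene-end shares were 15.01% and 13.7%. Genes with a peak in sh-VNGD only numbered 629, and the peak ratio was 1.28 on chromosome X and 1.07 on chromosome 19. A −log10 q of 5 in both lists gave overlaps of 73.1% and 51.7%, a 50% reciprocal overlap 66.1% and 46.6%, and equal numbers of peaks 61.9% and 61.8%, with a sh-VNGD gene-end share of 7.77%. Within 500 bp the gene-end shares were 5.81% and 4.35%, smaller by construction.

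Scaling to the median of genes set the median gene-end log2 ratio to 0 by construction and turned 5 reported list medians positive: hepatocyte markers 0.265, immediate early genes 0.0745, keratinocyte markers 0.0294, interferon response 0.0162 and nucleotide excision repair 0.00566. Among named genes with an interval apart from 0, HMGB2 became 0.0699. Fold enrichment in place of pileup gave a median of −0.11 and turned BRCA1 to 0.0162, BRD9 to 0.0543, GAPDH to 0.23, H4C5 to 0.47, HMGB2 to 0.43 and PGK1 to −0.0799. It moved 34 more named genes outside their intervals, among them CDT1 to −0.13, CHEK1 to −0.09 and CHD4 to −0.42. Fold enrichment was not scaled to kept tags, and its level of −0.11 for all genes was set against intervals of a ratio with a level of −0.45. Part of these moves and sign changes can thus come from the differing level. Tags within 10 kb moved 24 named genes, among them GPX2 to −0.79 and CATSPER3 to −0.59, and left 75 within their intervals. Own windows moved none of the 23 reported list medians or of 117 named genes outside the range set for each, but some lists changed place. Fanconi anaemia genes went from a median of −0.59 (percentile 5.66) to −0.62 (percentile 2.1), below the percentile of 2.5 that bounds the matched range. Osteoblast and neuronal lists went from −0.50 and −0.54 to −0.40 and −0.41, above the −0.45 of all genes. Nucleotide excision repair went from −0.44 to −0.47, below that level. In the simulation, which raised sh-VNGD pileups by the ratio of kept tags, 78% of 0.5-fold differences had an interval beyond 0. Real gene-end pileups were about equal, at medians of 75 tags in sh-ctrl and 73 in sh-VNGD, so this share need not hold for them.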

Other observations

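The tests behind the values in this part were chosen after the data were seen, and they are given without explanation. Ends of long non-coding RNA genes away from protein-coding ends had a median log2 ratio of −0.33 in 4621 regions, with median pileups of 29 tags in sh-ctrl and 32 in sh-VNGD. Small nuclear RNA genes, which encode splicing RNAs, stood at −0.59 in 78 regions, with median pileups of 78.5 and 81 tags, and transfer RNA genes at −0.39 in 204 regions, with 53 and 52. Pseudogenes stood at −0.23 in 2371 regions, whose pileups were low, at medians of 18 and 21 tags. The median was −0.45 at ends of protein-coding genes. Over all shared regions the median went from −0.19 at low to −0.49 at high pileups, where calling in both libraries limits the ratios of low regions.

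HMG box and architectural genes, unremarkable by summit pileup, were low by tags within 10 kb, at a median log2 ratio of −0.52 against −0.32 for all genes and percentile 0.30 of 1000 matched lists. Interferon response genes stood at −0.12 and percentile 95.7 by the same reading.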
